A study of Mus musculus with 6 samples.

How the data were processed

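RNA of the mouse trigeminal ganglion, the sensory ganglion of the face and jaw, was measured in 6 libraries. Wild-type animals had been injected with complete Freund's adjuvant (CFA, an oil emulsion that raises local inflammation) or with saline, and tissue was taken on day 3, with 3 libraries per group. Per the labels, poly(A) RNA was selected with an NEBNext module, libraries were made with a KAPA stranded kit, and the samples held neurons and glia. The design text names an Illumina NovaSeq as the sequencer. Where the injection was made is not given in the sources used here. The libraries are described as tissue of injected mice, 3 per group, without naming single animals, so p-values measure the spread between these libraries.

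Expression values were deposited by the authors as FPKM (fragments per kilobase of transcript, scaled to all mapped fragments), per the file headers, in 1 table with 13673 rows, all of them protein-coding genes. The build was GRCm38, per the submitters' processing notes. The aligner, the quantification tool, the annotation release and whether strand was used in quantification are not given in the sources used here. Tested on the values, the larger of the 2 group means was at least 0.501 FPKM in every row, so rows below a group mean of 0.5 had been left out before deposit. Genes without a row, Ifnb1 among them, were not analysed here. In addition, 1 line of the table had been emptied for this work. In 82 rows at least 1 library was listed at 0. Gene symbols, identifiers and coordinates were taken from the table, and 13662 identifiers matched GENCODE M21 (GRCm38), with identical coordinates in 12555. That annotation gave transcripts per gene and exons shared with a neighbouring gene.

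FPKM totals per library ran from 261183 to 275152 and medians from 5.41 to 5.73. These totals are not read depths. A search for whole-read steps in the low values of genes with 1 annotated transcript gave a strongest step strength of 0.159, where 1 would mean that all values were whole multiples. Depth is therefore unknown, and no counting interval or detection floor is given. Rank correlations across genes ran from 0.957 to 0.972 within groups and from 0.954 to 0.973 between them, so no 2 libraries looked like 1 library deposited a second time.

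For each gene with a mean of at least 1 FPKM over the 6 libraries, log2(FPKM + 1) was compared between groups with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). No covariate was used. P-values were adjusted by the Benjamini-Hochberg method over the 12238 genes tested, and a gene was called at an adjusted p below 0.05. Fold changes on this scale understate the change of genes with low FPKM. A second count took genes at an unadjusted p below 0.05 and a change of 1.5-fold or more. All tests were two-sided. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so none is reported for single genes.

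Before the data were examined, 34 gene lists were fixed from general knowledge of the ganglion, of inflammation and of tissue that dissection can carry along. The 30 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists. Beside it stand camera with a correlation estimated per list, fry, and the members past 0.05 when adjusted over the list alone. The main design, the alternatives and the rule for named genes were fixed at the same time. That rule names Irf7 and Ifnb1 from the series title, the 12 strongest rises and falls whose groups do not overlap (called genes first, then by p), up to 4 members of each called list and of both interferon lists, and 1 member of each other list. Predicted gene models were skipped. Where the members past the threshold over a list alone are given, or all lower members of a list, some go beyond this rule. Other genes named outside it are said to have been chosen after their values were seen. Results of a few single genes are not reported here.

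The same functions were tested on simulated data with the real means and within-group spreads, 12220 genes and changes of known size. The test recovered 19.4% of 1.5-fold, 64.2% of 2-fold and 77.3% of 4-fold changes, with 6 false calls among 113. Independent noise was simulated, without the shared variation between genes that real dissections carry.

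Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, rescaling each library to a common total, median-of-ratios factors, quantile normalization, eBayes with robust variances or without trend, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were log2(Gh + 1) as a covariate, limma's library quality weights, leaving out both libraries numbered 3, and leaving Ttr out of its list. Figures were drawn with matplotlib 3.10.9.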

Results

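The table covered 6 trigeminal ganglion libraries, 3 from mice given CFA and 3 from mice given saline, all at day 3. The series title concerns IRF7, a transcription factor that drives type I interferon genes, and interferon beta in inflammatory pain. The comparison asked which ganglion transcripts differed between CFA and saline. Values are FPKM, given as mean ± SD with n = 3 libraries per group, and log2 fold changes are CFA minus saline on the log2(FPKM + 1) scale with their standard error (SE).

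The interferon-responsive gene Ifi27l2a rose in the ganglia of CFA mice from 30.6 ± 2.59 to 83.5 ± 9.10 FPKM (SD, n = 3) and Oas1a, an antiviral 2'-5' oligoadenylate synthetase, from 1.25 ± 0.202 to 4.06 ± 0.259. At a preset correlation between genes, the lists of interferon-stimulated genes, MHC class I, MHC class II and macrophage markers rose as groups. None of these 4 lists was called with an estimated correlation (adjusted p = 0.233, 0.298, 0.298 and 0.238). The monocyte chemokine Ccl12 rose from 3.34 ± 0.310 to 8.0 ± 0.379. Known glucocorticoid-responsive genes fell as a group, with all 21 tested members lower under CFA. By far the strongest change of a single gene was in Ttr, which encodes the thyroxine carrier transthyretin, at 2.08 ± 0.184 FPKM with saline and 225 ± 36.3 with CFA, a 108-fold difference.

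Across the 12238 genes tested, limma called 7 at an adjusted p below 0.05, 4 higher and 3 lower. At an unadjusted p below 0.05 there were 1018 genes, where chance gives about 612, and 191 of these changed 1.5-fold or more, 126 higher and 65 lower. The 2 groups did not overlap in 1780 genes (14.5%, where chance gives 10%), and in 3346 genes when CFA replicates 1 and 3 and saline replicate 1 were set against the other 3 libraries. Apart from Ttr, the called genes stand close to the threshold. Ttr stayed called whichever library was left out, Ifi27l2a in 4 of the 6 such fits, Grm7 and Fopnl in 2, and Oas1a, Ccl12 and Fbxl17 in 1. Leaving out CFA replicate 2, CFA replicate 3, saline replicate 1 or saline replicate 2 gave 13, 13, 19 and 12 calls, of which 4, 3, 5 and 3 were among the 7, and leaving out CFA replicate 1 or saline replicate 3 gave 6 and 5, with Ttr the single shared gene in each.

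Interferon-stimulated genes had the smallest p of all lists by camera at the preset correlation. Of 43 tested members 41 were higher under CFA, 36 of them without overlap, and the mean log2 fold change was 0.56 (camera, adjusted p = 3.45e-30; adjusted p = 0.233 with an estimated correlation). Over all genes 2 members passed, Ifi27l2a (log2 fold change 1.42, SE 0.104, adjusted p = 0.0243) and Oas1a (1.18, SE 0.103, adjusted p = 0.0243), and 35 passed, all higher, when adjusted over the list alone. Ifit1, an interferon-induced RNA-binding protein, was listed at 45.7 ± 5.64 FPKM with CFA against 14.99 ± 4.86 (log2 fold change 1.58, adjusted p = 0.124 over all genes), and the secreted glycoprotein gene Lgals3bp at 16.3 ± 0.865 against 7.95 ± 1.43. The 2 members that were lower, Ly6e and Samhd1, did not pass over the list alone. Ifi27l2a lies on chromosome 12 at 103442167 to 103443680 and Oas1a on chromosome 5 at 120896256 to 120907521 (GRCm38). Several members, such as the Oas1, Ifit3 and Gbp genes, have close paralogs, and reads shared between copies leave their single values uncertain. The calls of Ifi27l2a and Oas1a both ended when CFA replicate 1 or saline replicate 3 was left out. They also ended with the replicate number as a block and with the Gh covariate. Among the fits without 1 library, Oas1a stayed called only without saline replicate 2. Their log2 fold changes stayed at 1.33 to 1.48 (Ifi27l2a) and 1.12 to 1.24 (Oas1a) without any one library. The list stayed called without any one library (mean log2 fold change 0.46 to 0.62).

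Irf7 itself was listed at 2.80 ± 0.620 FPKM with CFA and 1.13 ± 0.182 with saline, a 2.47-fold difference without overlap of the groups. Its log2 fold change of 0.83 (SE 0.141) did not pass over all genes (adjusted p = 0.179) and passed when adjusted over the list of interferon induction and signalling genes alone (adjusted p = 0.0209). In that list 3 of 27 tested members passed over the list alone, Irf7, Irf9 (5.34 ± 0.10 against 3.58 ± 0.374 FPKM) and Irf1 (6.42 ± 0.608 against 4.48 ± 0.306), and none passed over all genes by limma. The list as a whole rose by a mean log2 of 0.16 (camera, adjusted p = 0.00173; adjusted p = 0.429 with an estimated correlation). Irf7 lies on chromosome 7 at 141262706 to 141266481, and its exons overlap those of Phrf1 on the other strand. Ifnb1 was not analysed here. The list was no longer called over genes with a mean of at least 5 FPKM (adjusted p = 0.274), where Irf7 is not tested.

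**Figure D1:**
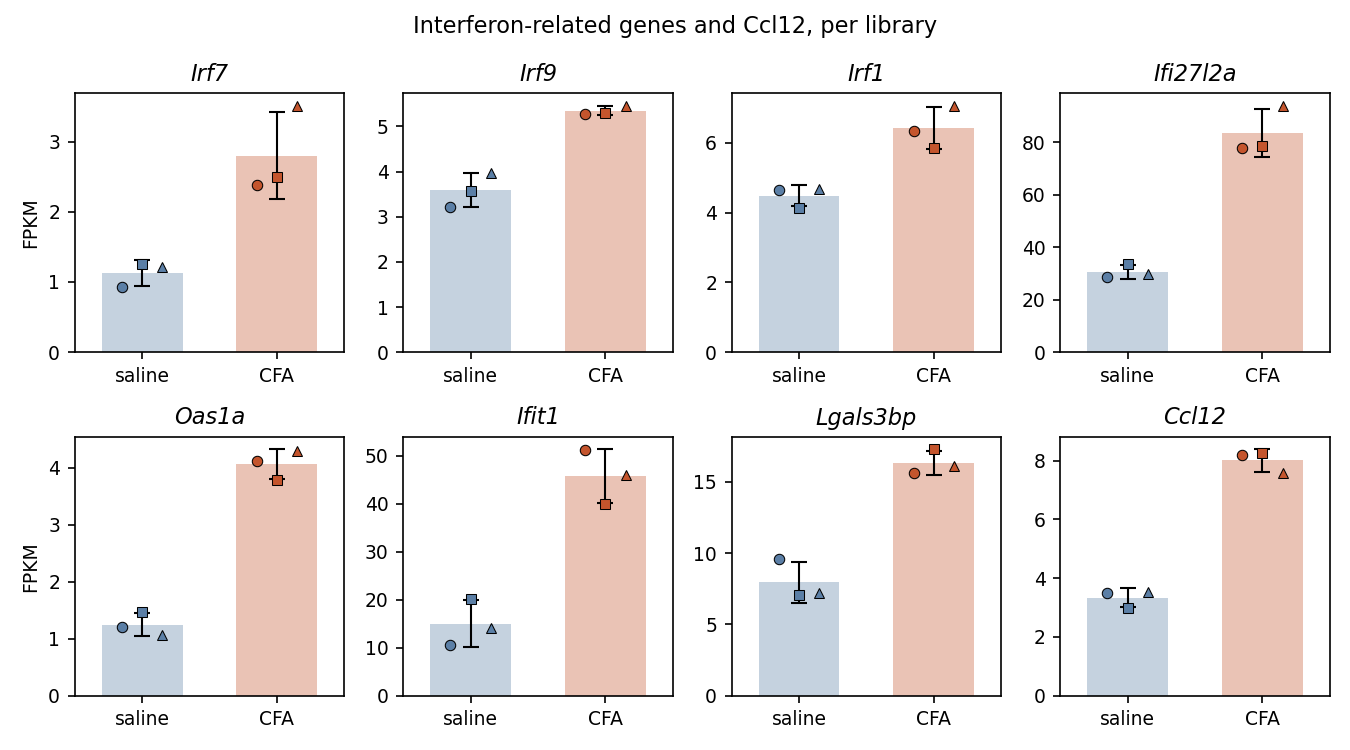
FPKM (linear axes from 0) of 8 genes in the saline (blue) and CFA (orange) libraries; bars are group means, error bars the SD of 3 libraries, and circles, squares and triangles are replicates 1, 2 and 3. In each panel every CFA library lies above every saline library, with Irf7 between 2.38 and 3.51 FPKM under CFA and between 0.922 and 1.26 under saline.

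The remaining called genes were a varied set. Ttr, on chromosome 18 at 20665250 to 20674324, had a log2 fold change of 6.19 (SE 0.129, adjusted p = 1.36e-05). Ccl12, on chromosome 11 at 82101845 to 82103400, rose by 1.05 (SE 0.0912, adjusted p = 0.0243). Grm7, the gene of a presynaptic metabotropic glutamate receptor on chromosome 6 at 110645581 to 111567230, fell from 8.73 ± 0.669 to 3.38 ± 0.334 FPKM (log2 fold change −1.15, SE 0.0976, adjusted p = 0.0243). Fbxl17, an F-box protein gene on chromosome 17 at 63057452 to 63500017, fell from 4.64 ± 0.10 to 1.84 ± 0.172, and Fopnl, a centrosomal protein gene on chromosome 16 at 14299244 to 14317375, from 35.7 ± 0.963 to 17.6 ± 1.64. Each of these 3 genes has 5 annotated transcripts, and exons of Grm7 and Fopnl overlap a gene on the other strand. Next among the higher genes, without passing over all genes, stood the creatine transporter Slc6a8 (12.2 ± 2.53 against 3.61 ± 0.472 FPKM, adjusted p = 0.0571), Tmem170b (4.12 ± 1.56 against 0.151 ± 0.0209), the clock repressor Nr1d1 (9.32 ± 0.266 against 4.77 ± 0.611), Eya2, the retinoic acid binding protein Crabp2 and the protease inhibitor Timp1 (5.11 ± 1.04 against 1.65 ± 0.268). Among lower genes short of the threshold were Cntf, a trophic factor of Schwann cells (101 ± 6.48 against 176 ± 9.50, adjusted p = 0.0553), the actin nucleation subunit Arpc4 (24.4 ± 2.51 against 45.8 ± 2.57), Pcmtd2, Angptl7, Etnppl and Tcim. Cntf and Arpc4 share exons with Zfp91 and Ttll3 on the same strand. Leaving out CFA replicate 1 or saline replicate 3, among others, ended the calls of Ccl12, Grm7, Fbxl17 and Fopnl, while their log2 fold changes kept their direction in each fit (Grm7 between −1.21 and −1.10). The replicate number as a block and the Gh covariate ended these calls as well.

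Antigen presentation genes were higher under CFA. All 17 tested MHC class I and antigen processing genes were higher, 12 without overlap, with a mean log2 fold change of 0.33 (camera, adjusted p = 1.73e-09; adjusted p = 0.298 with an estimated correlation). Adjusted over the list alone, 8 rose, among them H2-T23 (10.9 ± 1.26 against 6.75 ± 0.612 FPKM), H2-Q4, H2-D1 and the immunoproteasome subunit Psmb8 (9.64 ± 1.51 against 6.26 ± 0.531). Of 6 tested MHC class II genes 5 were higher, and 4 passed over the list alone: H2-Ab1, H2-Eb1, H2-Aa and the invariant chain Cd74 (90.5 ± 10.3 against 54.2 ± 17.2). The class II list had a mean log2 fold change of 0.41 (camera, adjusted p = 0.000251; adjusted p = 0.298 with an estimated correlation). None of these genes passed over all genes by limma, and class I genes are near-identical copies in part, so that reads can be split between them.

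Macrophage markers rose as a list, with 20 of 25 tested members higher and a mean log2 fold change of 0.23 (camera, adjusted p = 5.92e-07; adjusted p = 0.238 with an estimated correlation). Over the list alone 8 rose and 17 did not pass, and none passed over all genes. The lysosomal protease Ctss stood at 47.9 ± 2.92 against 29.0 ± 2.80 FPKM, Aif1 (IBA1) at 5.19 ± 0.424 against 2.58 ± 0.629, Pf4 at 7.89 ± 0.931 against 4.96 ± 0.324 and the complement subunit C1qb at 38.1 ± 3.25 against 25.2 ± 0.183. Ctss, Aif1 and C1qb are also expressed by microglia, and markers of central nervous system tissue were higher in the same libraries. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave the macrophage list its largest mean difference, 0.234 in size. The next split was close, at 0.230. Complement and acute phase genes rose by a mean log2 of 0.17 (camera, adjusted p = 0.00173; adjusted p = 0.484 with an estimated correlation), with Timp1, C1qb and C1qa past the threshold over the list alone out of 24 tested. C1qa, C1qb and C1qc belong to both lists. In another split the complement list had a larger mean difference than in the real one (0.26 against 0.17 in size). Without CFA replicate 2 or saline replicate 1 the complement list was no longer called (mean log2 fold change 0.13 and 0.089, adjusted p = 0.0528 and 0.0879). Inflammatory cytokines and chemokines were not called as a list (mean log2 fold change 0.08, adjusted p = 0.175), although Ccl12 passed over all genes and Csf1, a macrophage growth factor, was higher and the receptor gene Il6ra lower over the list alone. Leaving out saline replicate 3 brought that list past the threshold (0.15, adjusted p = 0.0285).

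No list of sensory neuron markers was called as a group. Peptidergic nociceptor markers (20 tested, mean log2 fold change 0.04, adjusted p = 0.925), non-peptidergic nociceptor and pruriceptor markers (21 tested, −0.05, adjusted p = 0.175) and large-diameter neuron markers (20 tested, 0.05, adjusted p = 0.804) were not called by camera, and no member passed over its list alone by limma. Calca, which encodes the pain-related peptide CGRP, was listed at 432 ± 22.7 against 364 ± 41.8 FPKM, the itch-neuron receptor Mrgprb5 at 4.0 ± 0.536 against 5.57 ± 0.138 and Pvalb at 193 ± 25.5 against 144 ± 17.0. Pain-related channels and receptors (33 tested, mean log2 fold change −0.08) missed the threshold at an adjusted p of 0.0532 (adjusted p = 0.484 with an estimated correlation), led by the potassium channel Kcna1 (9.38 ± 1.57 against 13.0 ± 1.63). That list passed when any one of CFA replicate 1, CFA replicate 2, saline replicate 1 or saline replicate 3 was left out (adjusted p = 0.0457, 0.0223, 0.0192 and 0.0281), with means of −0.070, −0.11, −0.12 and −0.048, and the mean was −0.0052 without both libraries numbered 3. Nerve injury and regeneration genes were not called (25 tested, −0.06, adjusted p = 0.696); Stmn4 (50.4 ± 5.93 against 33.2 ± 2.13) and Csf1 were higher over the list alone.

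Among glia and connective tissue, satellite glia markers moved both ways. The satellite glia list had a mean log2 fold change of 0.15 (camera, adjusted p = 0.0428; adjusted p = 0.389 with an estimated correlation). Over the list alone 3 members rose: Fabp7 (233 ± 22.9 against 136 ± 10.5 FPKM), Gfap, the intermediate filament of reactive glia (95.9 ± 3.58 against 59.6 ± 8.39), and Kcnj10. In the other direction 2 members fell, Cdh19 (22.6 ± 2.85 against 33.3 ± 1.64) among them. Without CFA replicate 1, CFA replicate 2, saline replicate 1 or saline replicate 3 this list was not called (adjusted p = 0.0772, 0.193, 0.0519 and 0.122), with means that stayed at 0.17, 0.14, 0.14 and 0.16, nor with median-of-ratios or quantile scaling. Schwann cell and myelin markers were not called (21 tested, adjusted p = 0.696), with Mag (44.4 ± 5.59 against 27.8 ± 4.37) and Gjb1 higher over the list alone. Fabp7, Gfap, Kcnj10 and Mag are also expressed by glia of the central nervous system, whose markers were higher as well. Fibroblast and meningeal markers rose by a mean log2 of 0.16 (camera, adjusted p = 0.0042; adjusted p = 0.337 with an estimated correlation). In that list Col1a1 (26.8 ± 1.05 against 21.2 ± 0.560), Col3a1, Col6a1 and Fmod rose and Ogn (162 ± 17.6 against 226 ± 20.4) fell over the list alone, and the call ended without CFA replicate 2 (adjusted p = 0.0984).

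Glucocorticoid-responsive genes fell as a list. All 21 tested members were lower under CFA, 15 without overlap, with a mean log2 fold change of −0.47 (camera, adjusted p = 2.45e-16), and this was the single list that stayed called with an estimated correlation (adjusted p = 0.0219). None passed over all genes by limma, and 14 passed, all lower, when adjusted over the list alone. The kinase gene Sgk1 was listed at 15.6 ± 0.999 FPKM with CFA against 27.2 ± 1.88 with saline (log2 fold change −0.76, SE 0.0841, adjusted p = 0.0571 over all genes). The metallothionein genes Mt2 (121 ± 14.7 against 215 ± 16.3) and Mt1 (85.8 ± 2.45 against 113 ± 6.76) and the arrestin-domain gene Arrdc2 (5.56 ± 0.363 against 8.40 ± 0.778) came next. Left out one at a time, no library ended the list's call (mean log2 fold change −0.53 to −0.40). One member, Lcn2, also belongs to the neutrophil and complement lists. The neutrophil list had a mean log2(FPKM + 1) of 5.08 in saline replicate 3 and of 2.17 to 4.12 in the other libraries. Circadian clock genes, which share Per1 with the glucocorticoid list, were not called (17 tested, mean log2 fold change 0.01, camera adjusted p = 0.966), while Nr1d1 and Dbp were higher over the clock list alone. Camera asks for a shift in 1 direction, so clock genes that move both ways can cancel. In fry's mixed test, which allows both directions, the clock list passed (adjusted p = 0.000883). Other lists not called by camera passed it too, such as nerve injury and regeneration genes (adjusted p = 0.00367).

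**Figure D2:**
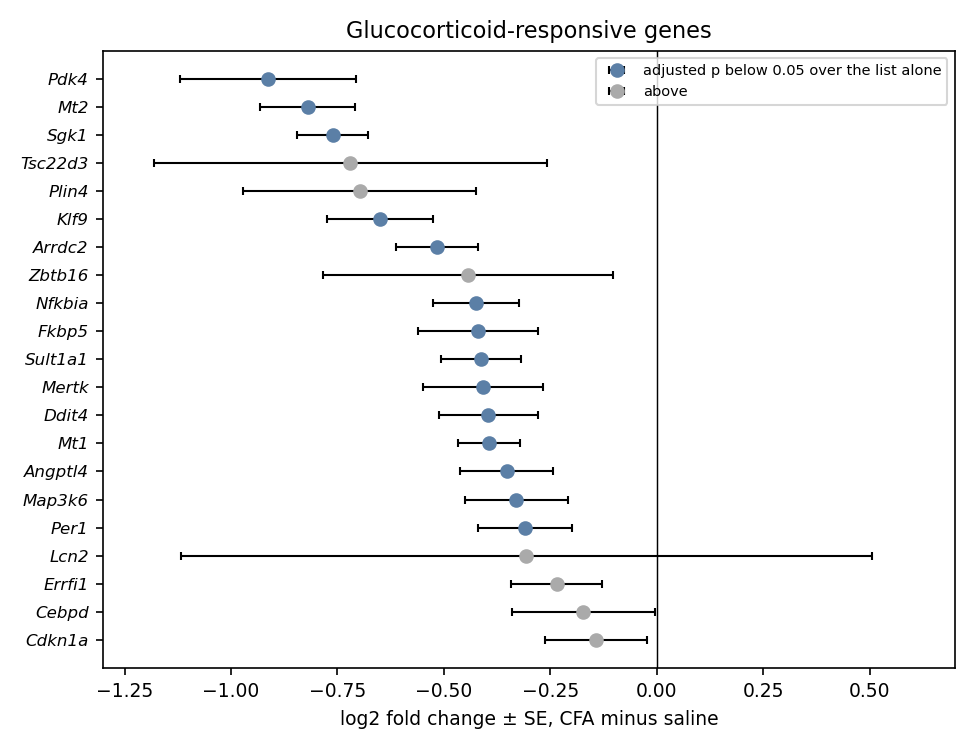
Log2 fold change (CFA minus saline, on the log2(FPKM + 1) scale) of the 21 tested glucocorticoid-responsive genes; points are limma estimates from 3 against 3 libraries, error bars 1 SE, blue for genes past an adjusted p of 0.05 over the list alone and grey for the others. All points lie below 0, and 14 are blue, with Sgk1 at −0.76 and Mt2 at −0.82.

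Nuclear-encoded oxidative phosphorylation genes were higher in 34 of 38 cases (mean log2 fold change 0.18, camera adjusted p = 1.89e-05; adjusted p = 0.484 with an estimated correlation), with Ndufc1 (46.8 ± 0.832 against 29.6 ± 3.88 FPKM) the one member past the threshold over the list alone. Cytosolic ribosomal protein genes were higher in 40 of 48 (mean log2 fold change 0.14, camera adjusted p = 0.00016; adjusted p = 0.587 with an estimated correlation), and none passed singly by limma. Mitochondrially encoded genes were lower in 13 of 13 (mean log2 fold change −0.39, camera adjusted p = 0.000251; adjusted p = 0.563 with an estimated correlation), none singly past the threshold by limma. CFA replicate 3 sets much of that fall: mitochondrial transcripts made up 7.24% of its FPKM total against 10.6% to 13.7% in the other 5 libraries, mt-Nd5 stood at 1121 ± 380 against 1644 ± 92.6 FPKM, and without that library the mean log2 fold change was −0.12. Without saline replicate 3 the mean log2 fold change was 0.11 for oxidative phosphorylation, which stayed called, and 0.071 for ribosomal proteins, which did not (adjusted p = 0.237). Both lists of nuclear genes lost their calls without the 2 libraries numbered 3 (adjusted p = 0.0779 for oxidative phosphorylation and 0.509 for ribosomal proteins), and the mitochondrial list lost its call with quantile scaling (adjusted p = 0.136). For each of these lists another split of the 6 libraries into 3 and 3 gave a larger mean difference in size. It was 0.19 against 0.18 for oxidative phosphorylation, 0.21 against 0.14 for ribosomal proteins and 0.51 against 0.39 for mitochondrially encoded genes.

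**Figure D3:**
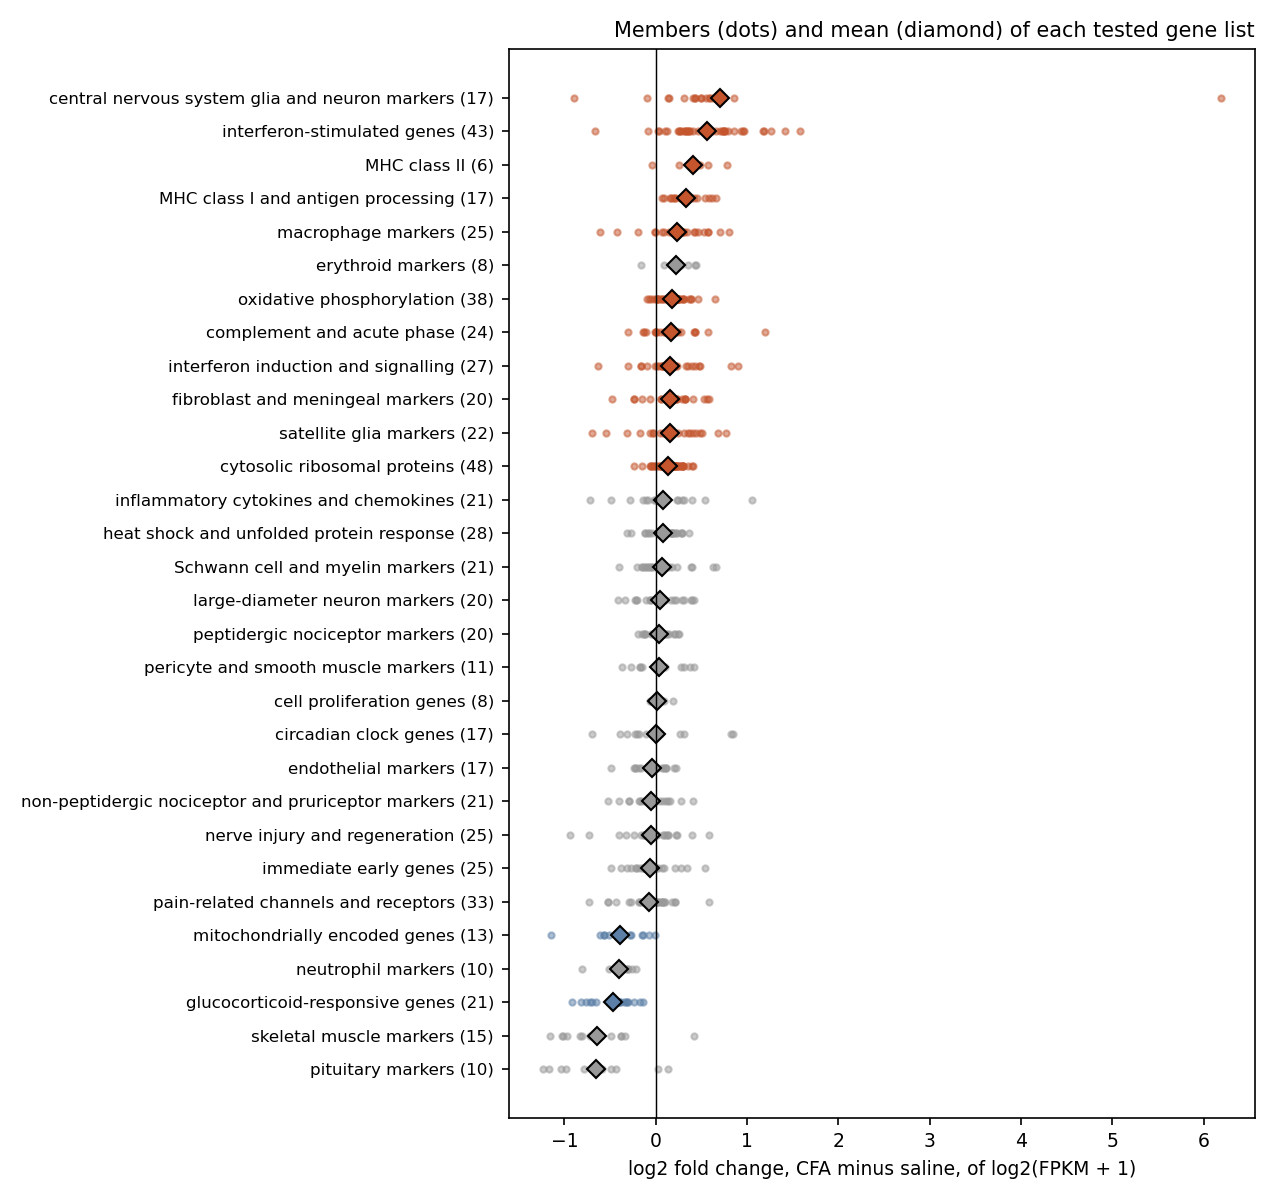
Log2 fold change (CFA minus saline, on the log2(FPKM + 1) scale) of the members (dots) and their mean (diamonds) for the 30 tested gene lists, with the number of tested members in brackets; orange and blue mark lists called higher or lower by camera at the preset correlation, grey those not called. Of the lists 11 were called higher and 2 lower, of which 1 stayed called with an estimated correlation and 3 by fry; the dot near 6.19 is Ttr.

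Markers of tissue outside the ganglion were present and differed between libraries. The list of central nervous system glia and neuron markers, which includes Ttr, rose (17 tested, mean log2 fold change 0.70, camera adjusted p = 4.61e-09; adjusted p = 0.27 with an estimated correlation). Besides Ttr, 7 members were higher over the list alone, among them the oligodendrocyte genes Hapln2 (13.9 ± 0.729 against 8.97 ± 1.07 FPKM), Ermn (32.2 ± 4.66 against 20.4 ± 2.20) and Mog (38.6 ± 3.04 against 24.2 ± 4.67). Without Ttr the mean was 0.36 (adjusted p = 1.12e-06; adjusted p = 0.306 with an estimated correlation). Pituitary markers were not called (10 tested, adjusted p = 0.197), yet growth hormone, Gh, stood at 947, 194 and 2363 FPKM in CFA replicates 1, 2 and 3 and at 2218, 157 and 3482 in saline replicates 1, 2 and 3. Saline replicate 3 stood apart, with Lipf at 713 FPKM where the other 5 libraries held 0.2 to 37.8, Ltf at 42.8 against 1.54 to 7.04 and the muscle actin Acta1 at 36.3 against 0.396 to 4.54 (Gh, Lipf, Ltf and Acta1 were chosen after their values were seen). Neutrophil markers (10 tested, mean log2 fold change −0.40, adjusted p = 0.244) and skeletal muscle markers (15 tested, −0.64, adjusted p = 0.101) were not called. Without saline replicate 3 the neutrophil, muscle and pituitary means lay above 0, at 0.59, 0.30 and 0.23, and none was called. Leaving out other single libraries brought lists past the threshold: neutrophil without CFA replicate 2 or saline replicate 2 (adjusted p = 0.0169 and 0.0402), and muscle (0.00491 and 0.000163) and pituitary (0.0476 and 0.000361) without CFA replicate 3 or saline replicate 2.

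**Figure D4:**
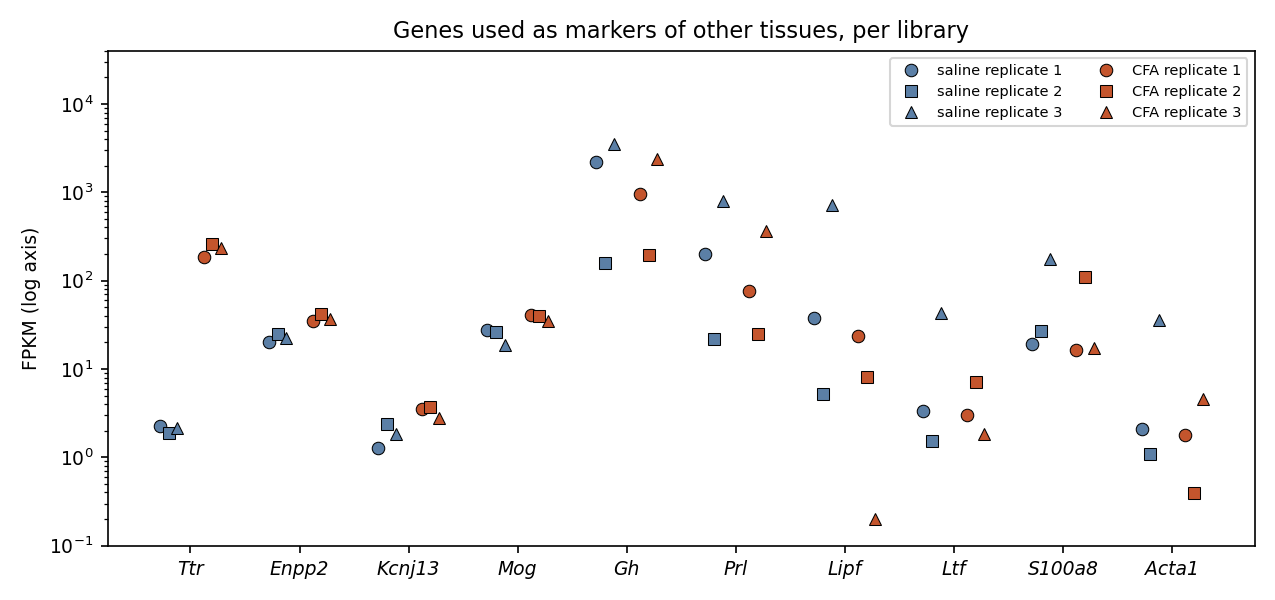
FPKM (log axis) of 10 genes used as markers of other tissues in each of the 6 libraries, blue for saline and orange for CFA, with circles, squares and triangles for replicates 1, 2 and 3. Ttr separates the groups in every library (1.88 to 2.25 against 186 to 258 FPKM), while Gh ranges from 157 to 3482 FPKM within the saline group alone.

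The other lists were not called: endothelial (17 tested, adjusted p = 0.244), pericyte and smooth muscle (11 tested, adjusted p = 0.588), erythroid (8 tested, adjusted p = 0.091), immediate early (25 tested, adjusted p = 0.173), heat shock and unfolded protein response (28 tested, adjusted p = 0.0962) and proliferation genes (8 tested, adjusted p = 0.89). Some of these passed without a single library: erythroid without CFA replicate 3 or saline replicate 3 (adjusted p = 0.0387 and 0.00456), endothelial and immediate early without saline replicate 2 (0.0317 and 0.0186), and heat shock without CFA replicate 2 (0.0223). The T and NK cell, B cell, melanocyte and sex-linked lists had fewer than 5 tested members (0, 3, 2 and 4) and were not tested as lists. Lck and Nkg7 were the T and NK cell genes with a row, both below a mean of 1 FPKM. Eif2s3y, on the Y chromosome, was listed at 13.9 ± 0.650 with CFA and 14.9 ± 1.56 with saline.

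By fry, which asks whether the genes of a list move one way on balance, 3 lists passed: interferon-stimulated genes (adjusted p = 0.0181), central nervous system markers (0.0181) and glucocorticoid-responsive genes (0.0176).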

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

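The Gh covariate, library quality weights, the fit without both libraries numbered 3 and the list without Ttr were chosen after seeing the data. Ttr was the single gene called under every alternative run (log2 fold change 6.08 to 6.68). Against 7 called genes (4 higher, 3 lower), rescaling to a common total gave 11 (5 lower), robust variances 13 (7 lower), a mean of at least 5 gave 6 lower, the Gh covariate 1 (1 higher, 0 lower in limma, with 67 lower at an unadjusted p below 0.05 and 1.5-fold) and the fit without both libraries numbered 3 gave 1 higher and 6 lower. Quality weights gave 266 (200 higher, 66 lower), with weights of 4.99 for saline replicate 2, 2.67 for CFA replicate 1 and 0.469 to 0.588 for the others, so that this fit rests mainly on 2 libraries. Leaving out 1 library gave 5 to 19 calls, 3 to 14 higher and 2 to 9 lower. Genes at an unadjusted p below 0.05 and 1.5-fold numbered 191, 304 with a pseudocount of 0.1, 100 with a mean of at least 5, 489 with quality weights and 165 to 264 without 1 library. The stricter filter tests fewer genes and leaving out a library uses fewer samples; for the other changes the cause was not tested.

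Called lists numbered 13, 1 with an estimated correlation and 3 by fry. Leaving out 1 library gave 12 to 18, and 9 of the 13 stayed called without any one library. Quality weights ended the calls of the fibroblast and satellite glia lists, and a pseudocount of 0.1 and the Gh covariate that of satellite glia. The neutrophil list changed sign, from a mean log2 of −0.40, not called, to 0.85, called, without both libraries numbered 3 (adjusted p = 0.0145, over a range of −1.04 to 0.59 without single libraries). Median-of-ratios and quantile scaling moved the median log2 fold change of all genes from 0.0052 to −0.0017 and −0.01. Irf7 stayed higher in every fit that tested it (log2 fold change 0.67 to 1.23, adjusted p 0.0353 to 0.393), below 0.05 with quality weights alone.

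With the replicate number as a block there was 1 call (1 higher, 0 lower in limma, with 87 lower at an unadjusted p below 0.05 and 1.5-fold). Deviations of same-numbered libraries correlated at 0.0803, 0.111 and −0.0475, which over all genes does not reach 0.1 in every pair, so the libraries were not treated as paired. CFA replicate 3, saline replicate 1 and saline replicate 3 did not correlate best with their own number. Gh and the scores on component 3 had the order replicate 2, 1, 3 in both groups, so a structure shared by number is left open.

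Of the 10 splits of the 6 libraries into 3 and 3, 3 called as many genes as the real one (7, highest other 10), 1 gave as many at the unadjusted threshold (191, highest other 149) and 4 called as many lists (13, highest other 14), the real split included. Genes without overlap numbered 1780 in the real split and 3346 in CFA replicates 1 and 3 with saline replicate 1 against the others, which points to a structure of the samples other than treatment. Splits of 6 libraries are too few for a share under 0.05. EdgeR, DESeq2 and the filter on counts were not run, since the table holds FPKM and no counts. Unknown depth leaves the counting error of low genes such as Irf7 and Oas1a unmeasured.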

Other observations

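The single genes in this paragraph lie outside the fixed lists and were chosen after their values were seen; none passed over all genes in limma, and no group of genes was tested with them. The oligodendrocyte kallikrein gene Klk6 stood at 36.5 ± 2.13 FPKM against 19.9 ± 3.18 (SD, n = 3), the transcription factor Nkx6-2 at 5.78 ± 0.531 against 3.00 ± 0.742 and the precursor-stage receptor Gpr17 at 2.10 ± 0.264 against 1.02 ± 0.245, with no overlap of the groups in any of these 3. Penk, which encodes the opioid precursor proenkephalin, stood at 9.66 ± 0.877 against 5.33 ± 0.757 (adjusted p = 0.151). The mast cell protease genes Cma1 (2.78 ± 0.269 against 1.39 ± 0.437) and Mcpt4 (3.70 ± 0.843 against 1.99 ± 0.460) were higher without overlap too, while Cpa3, another mast cell protease gene, was listed at 1.22 ± 0.384 against 1.56 ± 0.335.

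Of the 6 interferon-stimulated genes below the mean of 1 FPKM, and so outside the tests, Mx1 was listed at 1.30 ± 0.0952 with CFA against 0.489 ± 0.126, Zbp1 at 1.10 ± 0.127 against 0.396 ± 0.112 and Oas2 at 1.12 ± 0.297 against 0.391 ± 0.0371, each without overlap; the other 3 (Ifi44, Ddx60 and Oasl1) overlapped.

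In the 3 patterns that follow, the tests of choroid plexus, of central nervous system tissue, of circadian time and of macrophages were set, or had their bounds changed, after results were seen. For central nervous system tissue the first bound took no account of the spread; by it the value printed here would have counted against that explanation. For choroid plexus, 2 genes already seen to be higher were taken out of the test, and that the mean should hold with any 1 gene left out was added last. Without that last condition, the mean of 0.12 printed below would have counted for choroid plexus tissue.

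Ttr is the most abundant transcript of choroid plexus, the tissue that makes cerebrospinal fluid, so a trace of that tissue in the CFA dissections is a candidate explanation for its rise. Of 27 listed choroid plexus genes, 18 had a row and 14 were tested. Genes can lack a row because neither group mean reached 0.5 FPKM, and those without a row were not weighed. The 11 tested genes not looked at before had a mean log2 fold change of 0.12 (SE 0.0449 over libraries) and a median of 0.054. Of these, 7 were higher, 4 were lower and none passed the threshold over all genes. Without Kcnj13 the mean was 0.074 (SE 0.0404), so under the condition added last this explanation cannot be told apart from its absence. With Enpp2 (38.0 ± 3.80 against 22.6 ± 2.32 FPKM) and 1500015O10Rik the mean of 13 was 0.25 (SE 0.0535). Kcnj13 stood at 3.33 ± 0.505 against 1.84 ± 0.563. Below the mean of 1, Clic6 stood at 1.28 ± 0.245 against 0.688 ± 0.179 and Kl at 0.693 ± 0.114 against 0.354 ± 0.0910, each without overlap, while Prr32 and Trpm3 overlapped. All 14 tested genes had saline means above 1 FPKM too, but the filter selects for this. Sostdc1, Tmem72 and Igfbp2 differed by less than their SE. Sostdc1 and Igfbp2 already stood at 21.4 and 13.7 FPKM with saline, where a trace of tissue would show little. Aqp1 and Cab39l, also among the 11, had higher saline means than both. These genes cannot decide the question, and they limit what the mean and median of the 11 could show of a trace. Central nervous system tissue cannot be told apart either. Its oligodendrocyte genes were higher (0.48, SE 0.137), and its neuron genes gave 0.039 with an SE of 0.239. Of these neuron genes, Gabra6, Cbln1 and Neurod1 were higher (0.55, 0.50 and 0.14) and Camk2a and Slc17a6 lower (−0.89 and −0.10). Camk2a stood at 1.02 FPKM in CFA replicate 1 and at 7.02 to 9.46 in the other libraries, so 1 library weighs on that mean. Slc17a6 stood at 47.1 FPKM with saline, where a trace of other tissue would show little. Carry-over and a change of Ttr within the ganglion both stay open.

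The fall of the glucocorticoid-responsive genes does not rest on 1 library, since its mean log2 fold change stayed at −0.40 or lower whichever library was left out. Other tissue tracked by Gh is argued against as its cause, with a mean of −0.47 when log2 Gh was a covariate. Gh overlapped widely between the groups, so that fit speaks only to tissue that Gh tracks. Tissue marked by Ttr or the oligodendrocyte genes, which were higher under CFA, was not tested as a cause. Circadian time of collection cannot be told apart from treatment here: the clock output arm minus the Bmal1 arm gave 0.28 with an SE of 0.156, within which Nr1d1 and Dbp were higher and Per1 and Usp2 lower. Lower glucocorticoid signalling after CFA, or a difference in handling, is also possible and was not tested.

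For the interferon-stimulated genes, a macrophage increase of the size of the marker mean is argued against as the whole cause. Their mean log2 fold change exceeded that of the macrophage markers by 0.32 (SE 0.102). Markers in that list differed, however. Of 25 tested, 8 were higher over the list alone, with Aif1 at 0.80 and Ctss at 0.71, and 5 were lower. A larger increase of some macrophages is therefore not excluded. Summing of several transcripts per gene is argued against as well, with a mean of 1.05 over the 8 genes with 1 annotated transcript. An interferon response in the ganglion under CFA may underlie the rise and stays a hypothesis; in which cells it would lie, macrophages that changed included, was not tested.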
